A study of Homo sapiens with 6 samples.

How the data were processed

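Total RNA of H1299 cells, a human non-small cell lung carcinoma line, was measured on 6 arrays. The cells had been kept for 14 days with DMSO alone or with 500 nM PD 0332991 in DMSO, and each treatment has 3 arrays. Per the labels' protocols, the cells grew in RPMI medium with serum, and RNA was purified on columns. The labels name 2 sample preparation chemistries, the Affymetrix WT Plus kit in the sample description and a NuGEN amplification and biotin labelling kit in the labelling protocol, and do not settle which was used.

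The authors deposited 1 table of log2 values with 65535 transcript clusters and a column per array. That number equals the row limit of an older spreadsheet format less a header line, so the table may lack clusters of the array, and all counts of measured genes and list members refer to the clusters it holds. Per the submitters' processing notes the values came from Affymetrix Expression Console, whose version, background correction, summarisation and normalization are not given in the sources used here. The log base was read from the values, which ran from 1.87 to 19.9 and had medians between 4.85 and 4.98 per array. The highest values lie above 16, the log2 of the range of a 16-bit scanner, so the deposited scale is not a plain log2 of scanner brightness. All changes given here are differences on that deposited scale, and their size as a ratio of RNA amounts is uncertain. The table has no detection flags, scan dates or positions, so a floor per array and a batch of scanning were not examined. Levels near or below the array medians are not shown to be above background, so the size of a change into or out of them is uncertain. The number of arrays limits the precision: the median standard error of a log2 change was 0.0875.

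Gene names came from the platform annotation held for these arrays. Of the 65535 transcript clusters, 22685 were paired with 1 gene symbol, 1385 with several, and 41465 were not listed with a gene. Only those with 1 symbol were named and tested as genes. Of these, 20487 were matched by gene identifier to a RefSeq gene table of the assembly GRCh38.p14, used for names alone, and no symbol needed updating. For 296 genes with several probe sets, the probe set with the highest mean over the 6 arrays stood for the gene, which left 22375 genes. List members without a probe set of their own under this rule were not measured here. No filter on dim genes was applied in the main test. Coordinates are not given because the build of the deposited identifiers is not stated.

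The arrays were compared as PD 0332991 minus DMSO in R 4.3.3 with limma 3.58.1, using lmFit and eBayes on the deposited values without further scaling, 4 residual degrees of freedom per gene, and the Benjamini-Hochberg adjustment over the 22375 genes. A gene was called at an adjusted p under 0.05. The labels give both groups replicate numbers but do not say that a number marks a shared culture, so replicate number was not a term of the model. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 24 lists. Camera with an estimated correlation and limma's fry were the alternatives. All p-values are two-sided.

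The groups, the model, the 24 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups did not overlap. As applied, the rule left out symbols of unnamed loci, long intergenic, antisense, micro, small nucleolar and small nuclear RNAs, and olfactory receptors. It added from each list up to 3 called members with the largest change in size, and always RB1, CDK4, CDK6, CCND1, CCNE1, CCNE2, E2F1, CDKN1A, MKI67, LMNB1 and CD274. Other genes named in the text were chosen after their values were seen. The lists of neuroendocrine, of airway, alveolar and squamous, and of blood, endothelial and fibroblast markers served as measured values for cells of other kinds.

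The alternatives were centring each array on its median, quantile normalization, cyclic loess, leaving out dim genes, the mean of a gene's probe sets, all transcript clusters, eBayes with a trend and robust fitting, array weights, the replicate number as a block, a minimum change of 1, and leaving out each array in turn. Leaving out DMSO replicate 1 together with PD 0332991 replicate 2 was added after the data were seen. The comparison was tested on simulated data for 22375 genes with 200 changed. It recovered 52.2% of genes changed by 0.5, 97.0% of those changed by 1 and 98.5% of those changed by 2 on the log2 scale, and 8 of 173 calls were false. The data had 8529 called genes, and the adjustment depends on how many genes change, so these shares do not give the recovery in the data. In a separate simulated draw with no other changed genes, the shifted list was called, and 0 of 23 unshifted lists. Simulated genes were drawn independently of each other, so this cannot show how camera behaves where members of a list vary together. In the data the estimated correlation reached 0.522, in the mitotic list.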

Results

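The data were genome-wide transcript levels in H1299 cells, a human lung carcinoma line that makes no p53 protein and keeps the retinoblastoma protein pRB. The study compared cells given PD 0332991 (palbociclib), an inhibitor of the cyclin-dependent kinases CDK4 and CDK6, with cells given the DMSO vehicle. Each group had 3 arrays, taken after 14 days with 500 nM of the drug or with DMSO alone. These kinases phosphorylate pRB, and the study's title frames the treatment as a way to reactivate it, so the comparison asks which transcripts differ under the drug. The activity of pRB was not measured here. The median of the 65535 values per array lay between 4.85 and 4.98 on the deposited log2 scale. Pearson's r across transcript clusters, which are not independent replicates, was 0.993 to 0.995 within groups and 0.969 to 0.973 between them.

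PD 0332991 changed the levels of 8529 of the 22375 genes tested (38.1%), with 4382 higher and 4147 lower than in DMSO by limma. The deep changes were mostly falls: 156 called genes were lower by at least 3 on the log2 scale and 39 were higher by as much. Changes of at least 1 were found in 1011 genes that rose and 1215 that fell. Calls were concentrated in genes with high values, from 2.68% of the fifth of genes with the lowest mean level to 73.4% of the fifth with the highest. The 3 arrays of each group did not overlap in 10636 genes (47.5%), where chance gives 10%, and in 8498 of the called genes. DMSO replicate 1 and PD 0332991 replicate 2 lay together on the second principal component, which held 4.89% of the variance against 89.1% for the first, and without both arrays the count of genes changed by PD 0332991 was 7634. The labels do not say that the arrays of a group come from separate cultures, so the p-values measure only the spread between these samples.

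**Figure D1:**
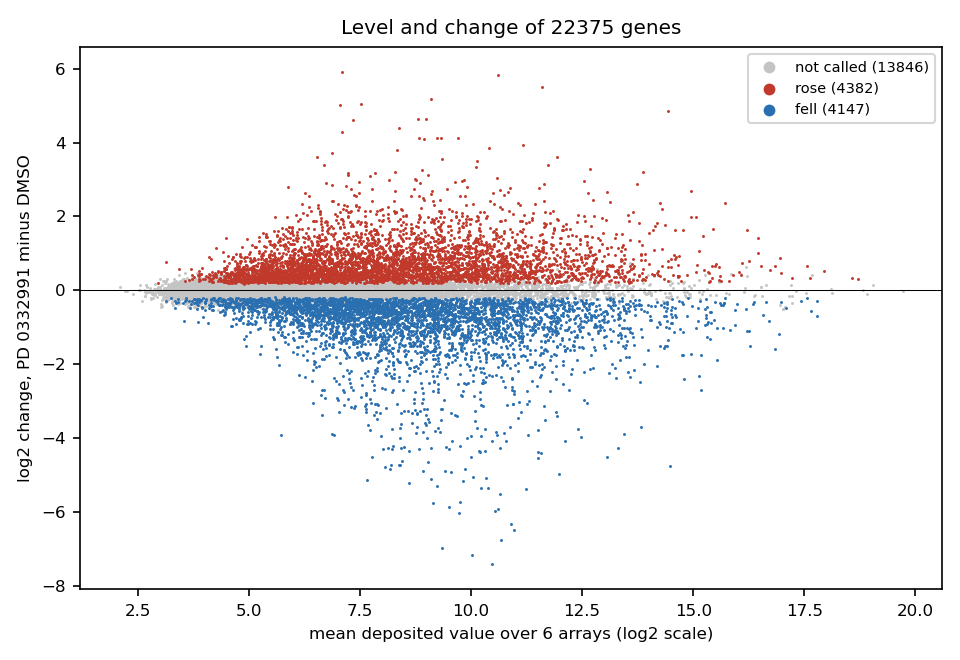
Log2 change (PD 0332991 minus DMSO) of 22375 genes against their mean deposited log2 value over the 6 arrays, each point a gene, with the 4382 genes that rose in red and the 4147 that fell in blue. The deepest changes are falls, reaching -7.42, while the highest rise is 5.92.

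The 8 largest falls were all in members of the mitotic or the DNA replication list. MKI67, whose product Ki-67 marks proliferating cells, fell by 7.42 ± 0.12 (SE, n = 3 per group), from 14.17 ± 0.24 (SD) in DMSO to 6.75 ± 0.03 in PD 0332991 (limma adjusted p = 1.15e-08). TYMS, the thymidylate synthase of DNA precursor supply, fell by 7.16 ± 0.07, and the mitotic kinesin gene KIF20A fell by 6.98 ± 0.09. The cyclin A2 gene CCNA2 fell by 6.76 ± 0.08, the condensin subunit gene NCAPG fell by 6.49 ± 0.08, and PLK1, a kinase of mitotic entry and spindle assembly, fell by 6.32 ± 0.09. FOXM1, a transcription factor of mitotic genes, fell by 6.02 ± 0.12, and the kinetochore gene NDC80 fell by 5.98 ± 0.09. Their adjusted p-values were at most 2.48e-08.

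The 8 largest rises included 3 members of the interferon response list, LGALS3BP, IFI44L and IFI6. MGP, which encodes a matrix protein that inhibits calcification, rose by 5.92 ± 0.22 (SE, n = 3 per group), from 4.14 ± 0.13 (SD) to 10.06 ± 0.49 (limma adjusted p = 4.14e-07). The laminin receptor gene BCAM rose by 5.83 ± 0.14, and IFI30, an interferon-inducible thiol reductase of lysosomes, rose by 5.51 ± 0.18. LGALS3BP, a secreted galectin-binding glycoprotein, rose by 5.18 ± 0.17, and MAP2, a microtubule-associated protein of neurons, rose by 5.04 ± 0.07. The interferon-induced genes IFI44L and IFI6 rose by 5.01 ± 0.13 and 4.87 ± 0.08, and ARRB1, which encodes a beta-arrestin, rose by 4.65 ± 0.09. IFI6 reached 16.87 ± 0.10, above the highest log2 that a 16-bit scanner gives, so the size of its change depends on the deposited scale. The DMSO levels of MGP, IFI44L and MAP2, 4.14, 4.55 and 5.01, lay below or near the array medians and were not shown to be above background, so the sizes and ranks of their rises are uncertain.

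**Figure D2:**
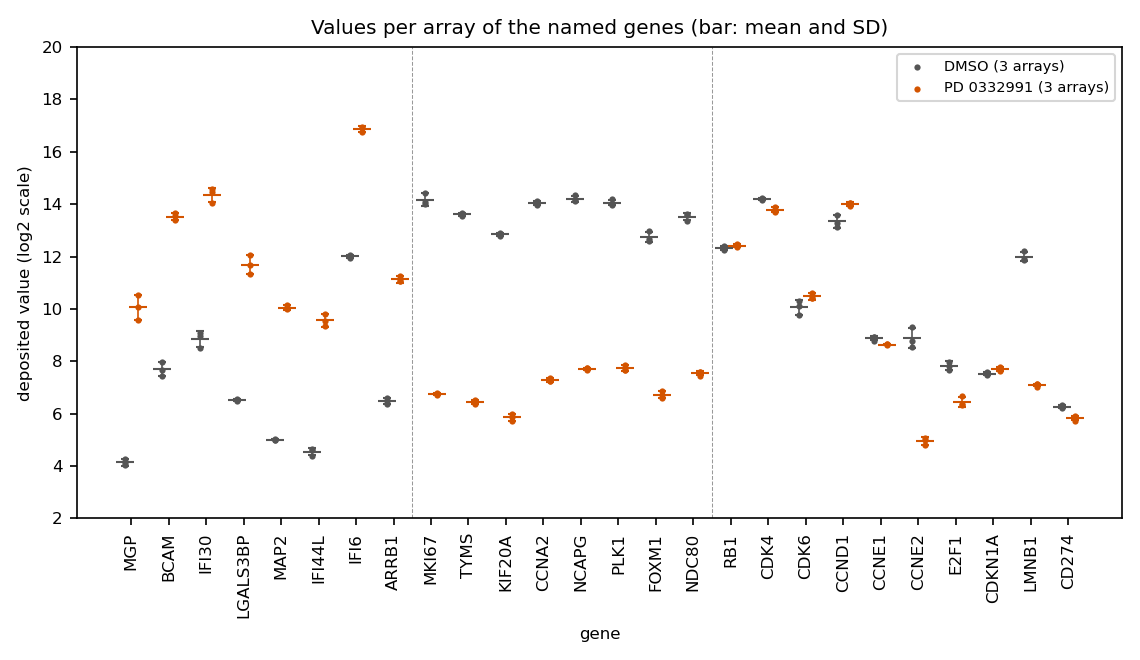
Deposited log2 values of 8 genes with the largest rise, 8 with the largest fall and 10 further genes named in advance, with a point per array, the group mean as a horizontal line and SD as error bars (DMSO grey, PD 0332991 orange, n = 3 each). MKI67 sits near 14.2 in DMSO and 6.75 in PD 0332991, and the RB1 groups overlap near 12.3 and 12.4.

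The machinery of DNA replication and mitosis fell as whole lists. All 48 measured DNA replication and S phase genes fell, and all 48 adjusted over the list alone, with a median log2 change of -2.76. Besides TYMS these included the primase subunit gene PRIM1, which fell by 5.51 ± 0.09 (SE, n = 3 per group), and the origin-firing factor gene MCM10, which fell by 4.77 ± 0.12. All 58 measured mitotic genes fell, and all 58 adjusted over the list alone, with a median of -4.28 and a range from -7.42 in MKI67 to -1.77 in SMC2. The 22 measured homologous recombination and Fanconi genes also fell, and all 22 adjusted over the list alone, with a median of -2.01. The nuclease gene EXO1 fell by 4.28 ± 0.09, RAD51AP1 fell by 4.25 ± 0.12 and the helicase gene BLM fell by 3.93 ± 0.10. LMNB1, the lamin B1 gene that is low in senescent cells, fell by 4.90 ± 0.10 (adjusted p = 2.68e-08). By limma's camera the adjusted p was 3.14e-35 for replication, 8.89e-48 for mitosis and 2.75e-16 for recombination. For each of the 3 lists it was adjusted p = 0.111 with an estimated correlation.

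Most measured histone genes whose transcripts are made in S phase fell, while H2AC6 rose. Of 21 measured replication-dependent histone genes 17 fell, 1 rose and 3 did not pass, with the same counts adjusted over the list alone and a median of -1.64. The linker histone gene H1-4 fell by 4.74 ± 0.13 (SE, n = 3 per group), H2BC10 fell by 4.74 ± 0.25 and H1-5 fell by 3.90 ± 0.26. The DMSO level of H1-4, 16.84, lay above the highest log2 of a 16-bit scanner, so the size of its fall depends on the deposited scale. H2AC6, named after its value was seen, rose by 3.40 ± 0.12 from 10.04 ± 0.21 (SD) to 13.44 ± 0.16 (limma adjusted p = 4.19e-07). The list's camera adjusted p was 4.30e-08, and adjusted p = 0.111 with an estimated correlation. The PD 0332991 level of H1-5, 3.79, also lay within the range of the fifth of genes with the lowest mean levels, so the size of its fall is uncertain. The list has 48 fixed members, and the others, among them members that share a transcript cluster with a near-identical gene, were not measured as single genes.

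Within the RB pathway, RB1 itself had a log2 change of 0.08 ± 0.07 (SE, n = 3 per group; limma adjusted p = 0.457), with overlapping groups. Of the 32 measured RB pathway genes 16 fell, 6 rose and 10 did not pass, the same counts as adjusted over the list alone. The repressor E2F genes E2F7 and E2F8 fell by 4.84 ± 0.11 and fell by 2.75 ± 0.13, CCNE2, for cyclin E2, fell by 3.92 ± 0.18, and the activator gene E2F1 fell by 1.38 ± 0.12. The PD 0332991 level of CCNE2, 4.97, lay within the range of the array medians, so the size of its fall is uncertain. Of the drug's targets, CDK4 fell by 0.40 ± 0.07 (adjusted p = 0.00279) and CDK6 rose by 0.42 ± 0.14 (adjusted p = 0.0429). The cyclin D1 gene CCND1 rose by 0.66 ± 0.12 (adjusted p = 0.00246), and CCNE1 fell by 0.25 ± 0.07 (adjusted p = 0.0238). CDKN1A, which encodes the kinase inhibitor p21, had a change of 0.17 ± 0.07 (adjusted p = 0.121), and passed with array weights (adjusted p = 0.0246). The list's median was -0.25 with a camera adjusted p of 0.00170, and adjusted p = 0.411 with an estimated correlation. The CDK6 call was lost when arrays were centred on their medians (adjusted p = 0.111) and without any single array except DMSO replicate 1 (0.0639 to 0.131), while CCNE1 lost its call with the replicate number as a block (0.0685) and without any single array except DMSO replicate 2 (0.0517 to 0.0735).

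Interferon response genes rose as a list. Of 39 measured members 31 rose, 0 fell and 8 did not pass, with 32 rising adjusted over the list alone and a median log2 change of 1.17. LGALS3BP, IFI44L and IFI6 led the list, as given above with rises of 5.18, 5.01 and 4.87. The members that did not pass included the antiviral genes MX1 at 0.08 and RSAD2 at -0.04. The levels of MX1 and RSAD2, 4.54 and 3.87 in DMSO and 4.62 and 3.83 under the drug, lay below every array median. MX1 and RSAD2 were not shown to be above background, so a lack of response in them was not shown. Uncalled members also included HERC5, with a change of 0.09 from a higher DMSO level of 8.42. Camera gave an adjusted p of 4.54e-15, and adjusted p = 0.111 with an estimated correlation. Genes of antigen presentation rose beside them: of 19 measured 14 rose, 1 fell and 4 did not pass, with 15 higher and 2 lower adjusted over the list alone, and a median of 0.70. The class I genes HLA-B and HLA-C rose by 1.91 ± 0.07 and 1.64 ± 0.07 (SE, n = 3 per group), and their light chain gene B2M rose by 1.63 ± 0.08. The peptide transporter gene TAP2 fell by 0.94 ± 0.09. The antigen presentation list had a camera adjusted p of 9.08e-06, and adjusted p = 0.284 with an estimated correlation. CD274, which encodes the checkpoint ligand PD-L1, fell by 0.45 ± 0.07 (limma adjusted p = 0.00138). The blood, endothelial and fibroblast markers had a median change of -0.05 in the same arrays.

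Lysosome and autophagy genes also rose. Of 34 measured members 29 rose, 1 fell and 4 did not pass, the same counts as adjusted over the list alone, with a median of 1.12. PSAP, the precursor of sphingolipid activator proteins, rose by 2.88 ± 0.07 (SE, n = 3 per group), from 12.3 to 15.2. The acid ceramidase gene ASAH1 rose by 2.62 ± 0.08 and the proton pump accessory gene ATP6AP1 rose by 2.37 ± 0.07. The member that fell was GLA, the lysosomal alpha-galactosidase, with a change of -0.65 ± 0.08. Camera gave an adjusted p of 2.74e-14, and adjusted p = 0.111 with an estimated correlation.

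**Figure D3:**
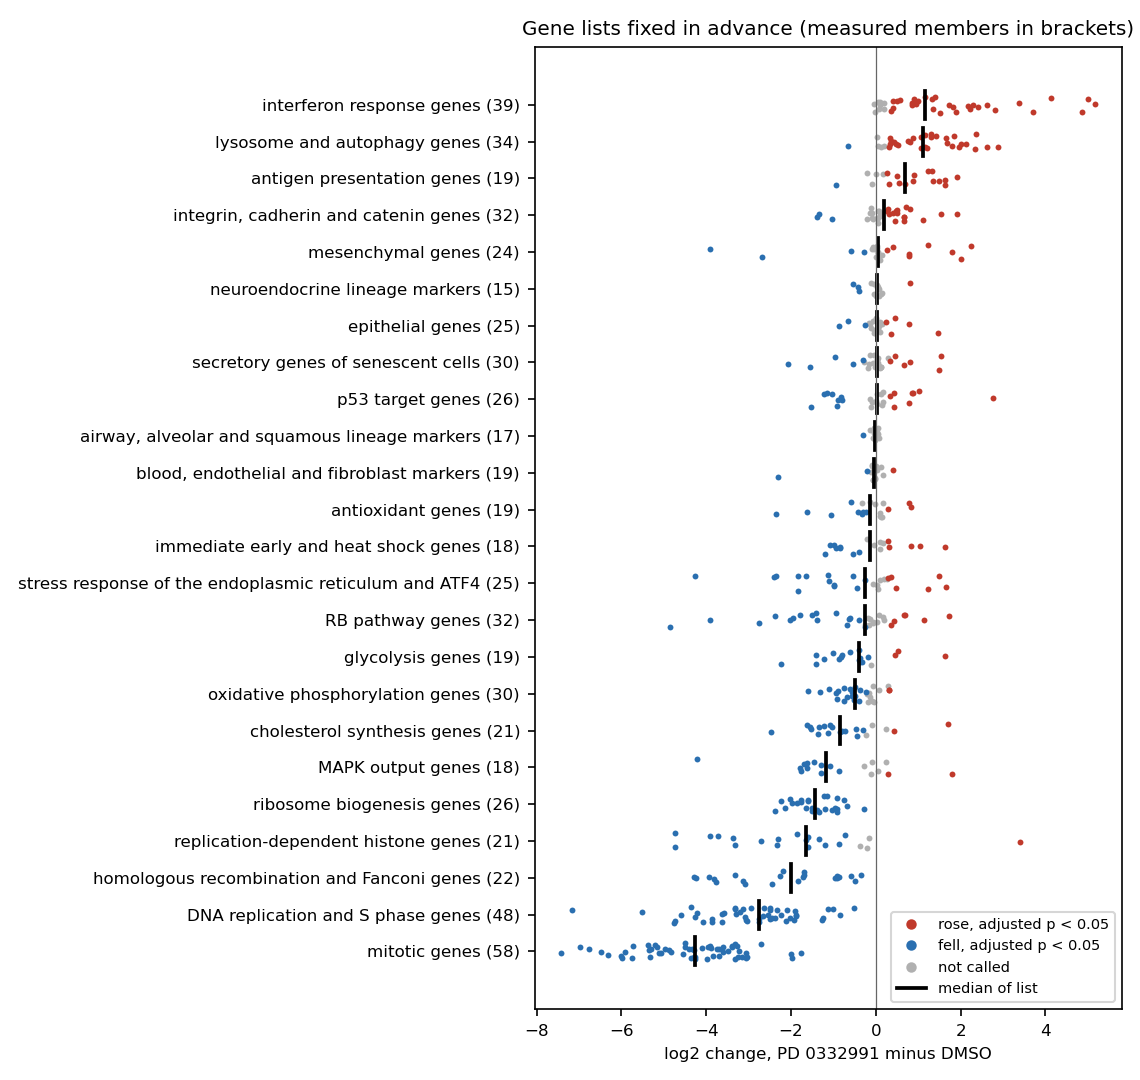
Log2 change (PD 0332991 minus DMSO) of the measured members of 24 gene lists, each point a gene, red where it rose, blue where it fell and grey where it was not called, with the list median as a black bar. The mitotic list lies lowest with a median of -4.28, and the interferon and lysosome lists lie highest at 1.17 and 1.12.

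Genes of ribosome biogenesis and of cholesterol synthesis fell as lists. All 26 measured ribosome biogenesis genes fell, and all 26 adjusted over the list alone, with a median of -1.44. The processing factor gene BOP1 fell by 2.38 ± 0.09 (SE, n = 3 per group), the nucleolar gene LYAR fell by 2.24 ± 0.10 and FBL, the fibrillarin gene, fell by 2.15 ± 0.08. Of 21 measured cholesterol synthesis genes 16 fell, 2 rose and 3 did not pass, with 17 lower and 3 higher adjusted over the list alone, and a median of -0.84. ACAT2, a cytosolic thiolase, fell by 2.46 ± 0.06 and TMEM97 fell by 1.61 ± 0.14, while the sterol reductase gene TM7SF2 rose by 1.71 ± 0.12. Camera gave adjusted p-values of 1.62e-17 for ribosome biogenesis and 3.31e-06 for cholesterol synthesis. Both had adjusted p = 0.111 with an estimated correlation.

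Genes of energy metabolism fell in both of their lists. Of 19 measured glycolysis genes 15 fell, 3 rose and 1 did not pass, the same counts as adjusted over the list alone, with a median of -0.41. The hexokinase gene HK2 fell by 2.25 ± 0.11 (SE, n = 3 per group) and PDK1, a kinase that restrains pyruvate dehydrogenase, fell by 1.42 ± 0.09, while the glucose transporter gene SLC2A3 rose by 1.63 ± 0.11. Of 30 measured oxidative phosphorylation genes 19 fell, 2 rose and 9 did not pass, with 20 lower and 2 higher adjusted over the list alone, and a median of -0.50. The cytochrome c gene CYCS fell by 1.61 ± 0.07, CYC1 fell by 1.31 ± 0.11 and COX8A fell by 1.10 ± 0.08. The DMSO level of COX8A, 16.80, lay above the highest log2 of a 16-bit scanner, so the size of its fall depends on the deposited scale. Camera gave an adjusted p of 0.000103 for glycolysis, with adjusted p = 0.129 with an estimated correlation. For oxidative phosphorylation it gave 9.08e-06, and adjusted p = 0.328 with an estimated correlation.

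In the list for the stress response of the endoplasmic reticulum and ATF4, SLC7A5, ASNS and SLC7A11 had the deepest falls. The amino acid transporter gene SLC7A5 fell by 4.26 ± 0.11 (SE, n = 3 per group), the asparagine synthetase gene ASNS fell by 2.40 ± 0.09 and the cystine transporter gene SLC7A11 fell by 2.34 ± 0.17. Of 25 measured members 13 fell, 6 rose and 6 did not pass, with 13 lower and 7 higher adjusted over the list alone, and a median of -0.24. Members that rose included SEL1L, of protein degradation at the endoplasmic reticulum, at 1.66, and the transcription factor gene DDIT3 at 1.50. Camera gave an adjusted p of 0.0351, and adjusted p = 0.419 with an estimated correlation. That call was also lost after quantile normalization (0.109), without the dimmest genes (0.0640 and 0.121), without DMSO replicate 1 (0.0623) and without PD 0332991 replicate 1 (0.0537). Among 19 measured antioxidant genes 8 fell, 3 rose and 8 did not pass, with 9 lower and 3 higher adjusted over the list alone, a median of -0.13 and a camera adjusted p of 0.238. Besides SLC7A11, which both lists hold, the glutathione synthesis gene GCLM fell by 1.61 ± 0.07 and the thioredoxin gene TXN fell by 1.05 ± 0.06.

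MAPK output genes fell, among them FOSL1, a member of the AP-1 transcription factors, which fell by 4.21 ± 0.18 (SE, n = 3 per group). The phosphatase gene DUSP5 fell by 1.79 ± 0.16, while SPRY1, a feedback inhibitor of receptor signalling, rose by 1.79 ± 0.11. Of 18 measured members 11 fell, 2 rose and 5 did not pass, with 11 lower and 3 higher adjusted over the list alone, and a median of -1.19. Camera gave an adjusted p of 0.000102, and adjusted p = 0.111 with an estimated correlation. The immediate early and heat shock genes went both ways. Of 18 measured members 8 fell, 5 rose and 5 did not pass, the same counts as adjusted over the list alone, with a median of -0.13 and a camera adjusted p of 0.303. JUNB rose by 1.64 ± 0.17, and the chaperone genes HSPE1 and HSPH1 fell by 1.19 ± 0.08 and fell by 1.09 ± 0.07.

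The secretory genes of senescent cells were not called as a list by camera. Of 30 measured members 6 rose, 5 fell and 19 did not pass, the same counts as adjusted over the list alone. The urokinase receptor gene PLAUR fell by 2.08 ± 0.13 (SE, n = 3 per group) and the urokinase gene PLAU fell by 1.56 ± 0.07, while the adhesion molecule gene ICAM1 rose by 1.53 ± 0.12. The cytokine genes IL6 and CXCL8 had changes of 0.10 and -0.15 that did not pass. Their levels lay below every array median in both groups, as did those of other uncalled members such as IL1A, CCL20 and MMP3. These genes were not shown to be above background, so a lack of response in them was not shown. The list's result therefore does not show that a secretory response was absent. The median was 0.03 and the mean -0.01, and camera's direction was upward (adjusted p = 0.934). The p53 target genes were likewise mixed in these cells without p53 protein, with 8 of 26 measured members rising, 8 falling and 10 not passing, the same counts as adjusted over the list alone. TP53INP1 rose by 2.75 ± 0.18, whereas the nuclease gene AEN fell by 1.53 ± 0.11 and the stress gene SESN2 fell by 1.22 ± 0.08. The median was 0.03, the mean -0.02 and camera's direction downward (adjusted p = 0.949).

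Adhesion genes rose more often than they fell. Of 32 measured integrin, cadherin and catenin genes 16 rose, 3 fell and 13 did not pass, the same counts as adjusted over the list alone, with a median of 0.18. The plakoglobin gene JUP rose by 1.91 ± 0.08 (SE, n = 3 per group), the integrin gene ITGAV rose by 1.53 ± 0.08 and ITGA6 fell by 1.38 ± 0.08. Camera gave an adjusted p of 0.0141, and adjusted p = 0.261 with an estimated correlation. Of 24 measured mesenchymal genes 8 rose, 4 fell and 12 did not pass, the same counts as adjusted over the list alone, with a median of 0.05 and a camera adjusted p of 0.204. CCN1 and CCN2, matricellular targets of the YAP coactivator, fell by 3.91 ± 0.12 and fell by 2.69 ± 0.20, and the fibronectin gene FN1 rose by 2.25 ± 0.09. Of 25 measured epithelial genes 5 rose, 3 fell and 17 did not pass, the same counts as adjusted over the list alone, with a median of 0.03 and a camera adjusted p of 0.629. The splicing regulator gene ESRP1 rose by 1.48 ± 0.11 and the keratin gene KRT8 by 0.79 ± 0.08, while the tight junction gene OCLN fell by 0.87 ± 0.06. The DMSO level of ESRP1, 4.90, lay within the range of the array medians, so the size of its rise is uncertain.

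None of the 3 lists of lineage markers was called by camera. Of 15 measured neuroendocrine markers 1 rose, 3 fell and 11 did not pass, the same counts as adjusted over the list alone. The granin genes CHGB and SCG2 changed in opposite directions, CHGB by 0.80 ± 0.11 and SCG2 by -0.54 ± 0.08 (SE, n = 3 per group), and DLL3 fell by 0.42 ± 0.10. The list's median was 0.03 and its mean -0.02, and camera's direction was downward (adjusted p = 0.874). Of 17 measured airway, alveolar and squamous markers SOX2 alone was called and 16 were not, with 0 called adjusted over the list alone. SOX2 fell by 0.30 ± 0.10 (limma adjusted p = 0.0388), and the list's median was -0.02 with a camera adjusted p of 0.818. Of 19 measured blood, endothelial and fibroblast markers 1 rose, 2 fell and 16 did not pass, with 1 lower and 0 higher adjusted over the list alone, a median of -0.05 and a camera adjusted p of 0.571. CD68, a lysosomal glycoprotein abundant in macrophages, fell by 2.30 ± 0.11 from a high level of 12.7, PECAM1 rose by 0.40 ± 0.13 (adjusted p = 0.0453) and ITGAM fell by 0.22 ± 0.07 (adjusted p = 0.0398). The calls of 3 of these genes were lost with fewer arrays: SOX2 without any array except PD 0332991 replicate 3 (adjusted p from 0.0507 to 0.135), ITGAM without any array (0.0572 to 0.112), and PECAM1 without DMSO replicate 1 or 2 or PD 0332991 replicate 1 or 3 (0.0939 to 0.145). SOX2 was also lost with arrays centred on their medians (0.0604), PECAM1 and ITGAM with trend and robust fitting (0.0560 for both), and ITGAM with the replicate number as a block (0.0948). The levels of PECAM1, 3.53 in DMSO and 3.93 under the drug, and of ITGAM, 4.83 and 4.62, lay below every array median. PECAM1 and ITGAM were not shown to be above background, so their changes are uncertain.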

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

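Signals outside the named genes differed between PD 0332991 and DMSO as well, in a test of all transcript clusters that was planned. Of 41465 transcript clusters listed with no gene, limma called 4749 (11.5%), with 2614 higher and 2135 lower in PD 0332991. Of 1385 transcript clusters paired with several gene symbols, 429 (31.0%) were called, with 205 higher and 224 lower, and these hold list members such as histone genes that could not be named singly. The transcript cluster TC12002778.hg.1, listed with no gene, rose by 8.06 ± 0.20 (SE, n = 3 per group), from 4.59 to 12.7 on the log2 scale (limma adjusted p = 7.34e-07), though its DMSO level lay below the array medians and was not shown to be above background, so the size is uncertain. Groups of 3 arrays were too small for a test of single outlying values, and the design has 1 contrast, so no difference between contrasts was tested.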

How the results depend on the processing

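Leaving out DMSO replicate 1 and PD 0332991 replicate 2 together was chosen after the data were seen; the other alternatives were planned. The count of genes changed by PD 0332991 was 8529 as deposited and ranged from 7483 to 10296 over the other settings that tested the named genes at the same threshold, with 7483 to 8075 on leaving out 1 array and 7634 without both arrays above. It was 2226 with a minimum change of 1, which follows from the stricter threshold, and 12192 over all transcript clusters. The share of calls that were higher stayed between 47.6% and 52.3%, except for 45.4% with the minimum change. For samples with the same replicate number the deviations correlated at r = -0.33, -0.15 and 0.10. The highest correlation, r = 0.41, was between DMSO replicate 1 and PD 0332991 replicate 2. Those arrays shared a deviation that depended on level: -0.08 and -0.09 among genes with the lowest values, and 0.05 in each among genes with the highest. Such a shared spread could hide a pairing, so these correlations cannot decide whether the numbers pair the samples. With the replicate block 7708 genes were called, 7606 of them shared. Among 87 named genes, 1099 of 1131 values under 13 settings kept their call, 31 lost it in 5 genes (CDK6, CCNE1, SOX2, PECAM1 and ITGAM), 1 gained it (CDKN1A) and 0 turned direction. The arrays carry no detection flags, so how far signal over background limits dim genes is unknown; 2.68% of the fifth with the lowest values were called.

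For the 24 lists, 359 of 382 alternative values kept the call, and 15 values in 5 uncalled lists turned sign. With an estimated correlation 0 of the 15 camera calls held after adjustment, although 9 lists had an unadjusted p under 0.05, and fry called 18 lists. With that correlation the adjusted p was 0.111 for replication, mitotic, histone, recombination, interferon, lysosome, cholesterol, ribosome biogenesis and MAPK output genes, 0.129 for glycolysis, 0.261 for integrin, cadherin and catenin, 0.284 for antigen presentation, 0.328 for oxidative phosphorylation, 0.411 for RB pathway genes and 0.419 for the stress response of the endoplasmic reticulum and ATF4. That last list also lost its call after quantile normalization (0.109) and without the dimmest genes under the milder (0.0640) or the stricter (0.121) of 2 filters by level, and ranged from 0.0187 to 0.0623 on leaving out 1 array; the cause was not tested. With fry, which does not compare a list with other genes, the antioxidant (0.000512), mesenchymal (0.00135) and immediate early and heat shock genes (0.00554) gained a call. The value of 0.111 is 1 adjusted p shared by 9 lists, whose unadjusted camera p with an estimated correlation ran from 0.00681 to 0.0416. All 58 measured mitotic genes fell, yet that list's unadjusted p was 0.0289. With 6 arrays, failing this test therefore does not show that a list was unshifted.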

Other observations

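The symbol families, the tests of other cells, of interferon transcripts and of H2AC6, and the genes named in this part were chosen after the results were seen; the splits of the arrays and the test of scale were planned. Families of genes with a shared symbol stem, 118 with at least 8 called members, were tested for direction by Fisher's exact test, two-sided. It compared rises and falls among a family's called members with those among the other called genes, and uncalled members did not enter. After adjustment 40 families passed. Stems of mitochondrial ribosomal proteins fell: 39 of 50 MRPL genes were lower and 0 higher (adjusted p = 6.58e-11), and 23 of 27 MRPS genes were lower and 1 higher (3.10e-05). Of 24 NUP genes, mostly nucleoporins, 20 fell with 0 rising and a median log2 change of -1.20 (3.10e-05), and falls were found in 22 of 31 POLR genes of the RNA polymerases (4.16e-05) and 9 of 12 TIMM genes of mitochondrial protein import (0.0119). Of 11 CCT genes, mostly chaperonin subunits, 9 fell (0.0304). The medians of these families were below 0 under each scaling tried.

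Other symbol stems rose. Of 30 GOLGA genes, mostly golgins, 17 rose and 0 fell (Fisher's exact test, adjusted p = 0.000280), and 9 of 10 MAN genes, most of them mannosidases, rose with 0 falling (0.0205). Of 18 protocadherin genes of the PCDHB cluster 16 rose, with a median of 1.33 (0.000485), although near-identical copies in the PCDHB and GOLGA families can share probes and are uncertain as single genes. The small nucleolar RNA genes of the SNORA family rose in 28 of 64 and fell in 2 (3.10e-05), and the semaphorin genes SEMA rose in 11 of 20 (0.00852). The medians of these families were above 0 under each scaling tried. The SNORD stem, also of small nucleolar RNA genes, did not pass: of 173 measured 26 rose and 12 fell (Fisher's exact test, adjusted p = 0.117). Genes are not independent replicates, so these p-values describe this set of arrays.

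A few single genes are given as values only, with no test of them as a group. STING1, the adaptor of DNA sensing, rose by 2.15 ± 0.08 (SE, n = 3 per group; limma adjusted p = 5.95e-07), and the RNA sensor gene TLR3 rose by 1.59 ± 0.11. IFIH1 and RIGI, which encode cytosolic RNA sensors and are in the interferon list, rose by 1.90 and 1.52. CGAS, the cytosolic DNA sensor, fell by 1.10 ± 0.09, and the DNA methyltransferase gene DNMT1, a member of the replication list, fell by 2.53 ± 0.08.

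The first pattern weighed was the number of genes changed, 8529. A difference in scale between arrays is argued against, since forcing all arrays to the same distribution left 9024 calls. Of the 10 splits of the 6 arrays into 3 and 3, 1 split, the real grouping, gave as many genes, and the highest of the others was 0 (140 to 978 at an unadjusted limma p under 0.05). For gene lists the real grouping gave 15 calls and the highest other 13, so 1 of 10 splits gave as many, and camera with a preset correlation called at least 7 lists in every split. With 10 splits no share under 0.05 can be reached. Every other split has arrays of both treatments on each side. Part of the drug difference thus remains between the sides, and it also widens the spread within them. The counts of the other splits are therefore not a rate of calls by chance.

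The second was the rise of the interferon response genes, with a median of 1.17. Cells of another type stay open as a source: the highest median change of the markers of any of the 5 cell types in the blood, endothelial and fibroblast list was 0.075, for fibroblasts, but only 1 of these markers, CD68, lay above the median level of all genes. CD68 fell by 2.30, from a level of 12.7 at which a small share of other cells would not show. Higher transcript levels of interferon genes may contribute: 1 of 21 measured interferon genes rose, IFNE by 1.01 (limma adjusted p = 0.00965), and 1 fell, IFNA10 by -0.55. This too stays open because 0 of the 21 had a mean level above 5.87, the median of all genes, and a direct effect of the drug was not tested.

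The third was the rise of H2AC6 by 3.40 while other replication-dependent histone genes fell. Signal shared with another measured H2A gene is argued against, since the highest change among 25 other H2A genes and transcript clusters was 0.39. Of the 13 other H2A genes measured singly, 9 fell and 0 rose, and 0 of 12 shared transcript clusters rose. No biological explanation of the H2AC6 rise was tested.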
